A study of Homo sapiens with 6 samples.

How the data were processed

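Poly(A) RNA was sequenced from 6 libraries of organoids derived from the H9 human embryonic stem cell line at day 30 of differentiation, per the labels. The deposited table gives TPM values for 62754 Ensembl genes, made by the authors with STAR 2.7.10a and RSEM 1.3.1 against GRCh38, per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here. Of the gene identifiers, 62700 carried a symbol and 58261 (92.8%) were in GENCODE 29, which was used for gene positions and types. TPM keeps no sequencing depth, so no counting error could be attached to a value, and a gene at 0 is given as listed at 0. RSEM divides reads shared by near-identical genes, so values of pseudogenes and close copies are uncertain. Raw reads were not used here.

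Groups were taken from the labels: hmSpVO (2 libraries), and C3, C4, C6 and hmSpVO_ventr (1 each). C3, C4, C6 and hmSpVO replicate 1 were prepared with the TruSeq kit and read on a HiSeq instrument, and hmSpVO replicate 2 and hmSpVO_ventr with the TIANSeq kit and a NovaSeq instrument, per the labels. The hmSpVO pair therefore spans both kits, and each comparison holds 1 difference within a kit, which is printed beside its count.

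From the table, log2(TPM + 1) was computed for the 18894 genes at 1 TPM or more in at least 1 library. All 6 libraries entered one limma model with 5 groups and a mean-variance trend, which leaves 1 residual degree of freedom (prior 1.314), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. hmSpVO was compared with C3, C4, C6 and their average, and hmSpVO_ventr with hmSpVO. A kit term would leave no residual degree of freedom. As a description of size with no p, genes were counted whose log2 difference was at least 2 in the same direction against both hmSpVO libraries, and for the average, genes whose gap between the sets of libraries was at least 2. C3, C4 and C6 were compared pairwise by the same cutoff.

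Gene lists of regional identity, neuronal class, other tissues and cell state (36 lists, 507 genes, 12 of them missing from the table) were fixed before the data were examined, as were the comparisons, tests and rule for naming genes. Some genes belong to several lists, so results of different lists are not independent. Each list was summarised by the median log2 difference of its tested members, its percentile among 10000 random lists matched in 20 bins of expression, the members higher or lower against both hmSpVO libraries, and the members past limma when adjusted over the list alone. A percentile describes these libraries and is not a test of the conditions, since genes of a list can vary together. Named genes are the 12 highest and 12 lowest of each comparison (5 and 5 among C3, C4 and C6) and up to 4 members of each list. TUBB3, POU4F1, PHOX2A, NEUROG1 and INA are list members outside that rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

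The pipeline was tested on simulated data for hmSpVO against C3, with normal noise whose SD (0.41) was set from the median absolute difference of the hmSpVO pair. That SD is the noise of a single library, while the differences of the real pair have an SD of 0.77, so these values are not on the same scale. The noise also lacks the wide tails of the real pair, so the count among unchanged genes below holds for that noise only. limma called 0 of 100 genes made 8-fold different and 0 of 100 made 64-fold different. The 4-fold count found 94 and 100 of them, and 1 of 18694 unchanged genes. Of 200 random lists, 12 lay outside the central 95% of their own random lists. Their genes were drawn at random, so this does not check lists whose genes vary together.

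Alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, limma without trend, each hmSpVO replicate left out, and C3, C4 and C6 as one group with and without a kit term. A count of protein-coding genes alone was added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.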

Results

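Bulk RNA was profiled in organoids grown for 30 days from H9, an established human embryonic stem cell line. The series title places the hmSpVO organoids in the region of the spinal trigeminal nucleus of the medulla, a hindbrain relay for sensation from the face. The 6 libraries fell into 5 groups, with 2 libraries of hmSpVO and 1 each of C3, C4, C6 and hmSpVO_ventr. The labels do not say what sets C3, C4 and C6 apart, nor what "ventr" stands for, so these names are used as given, and C3, C4 and C6 were not treated as replicates. C3, C4, C6 and hmSpVO replicate 1 were made with a TruSeq stranded kit, while hmSpVO replicate 2 and hmSpVO_ventr were made with a TIANSeq kit and read on another instrument. The values are TPM, which sum to about 1000000 in each library, so sequencing depth is unknown and no counting interval can be given. Between 14919 and 16431 genes per library reached 1 TPM. Mitochondrially encoded transcripts took 16.1% of the total in C3, 15.9% in C4, 10.4% in C6, 11.7% and 9.35% in hmSpVO replicates 1 and 2, and 6.72% in hmSpVO_ventr. Values of hmSpVO are means ± SD (n = 2), and all others come from 1 library with no replicate check.

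Neural and hindbrain genes were expressed in all 6 libraries. TUBB3, a neuronal tubulin, lay between 1549 TPM (hmSpVO_ventr) and 2000 TPM (hmSpVO replicate 2), and the neural progenitor factor SOX2 between 159 TPM (C3) and 364 TPM (hmSpVO_ventr). HOX genes, which mark position along the hindbrain and spinal cord, were present in paralogue groups 2 to 4 in every library, the lowest being HOXC4 at 6.92 TPM in hmSpVO_ventr. HOXB2 ranged from 103.5 TPM (C3) to 186 TPM (hmSpVO replicate 1) and HOXD4 from 19.3 TPM (hmSpVO_ventr) to 162 TPM (hmSpVO replicate 2). Of the 24 genes listed for paralogue groups 6 to 13, only HOXB8 and HOXB9 reached 1 TPM in any library, with at most 2.1 and 1.36 TPM. Of the pluripotency list, POU5F1 was listed at 0 in every library, while DPPA4 ranged from 4.89 TPM (C4) to 34.9 TPM (hmSpVO_ventr) and DNMT3B from 27.1 TPM (C3) to 75.6 TPM (C6). The 4 tested genes of that list were higher in both hmSpVO libraries than in C3 and C4, with medians of 0.66 and 0.62 (percentiles 98.5 and 99.13) and 0 passing limma over the list alone. Listed markers of other tissues were mixed. Low in all 6 libraries were SOX17 (endoderm) at 0.04 TPM or less, PECAM1 (endothelium) at 0.13 TPM or less, MYOD1 (muscle) at 0.16 TPM or less and PTPRC (blood cells) at 0.08 TPM or less. Others were not low, with the epithelial genes KRT8 and EPCAM at 33.6 and 32.2 TPM in C4, the matrix genes LUM at 75.5 TPM in C4 and DCN at 21.8 TPM in C3, the embryonic globin HBE1 at 16.2 TPM in hmSpVO replicate 1, and the junction gene CLDN5 at 28.1 TPM in hmSpVO_ventr.

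**Figure D1:**
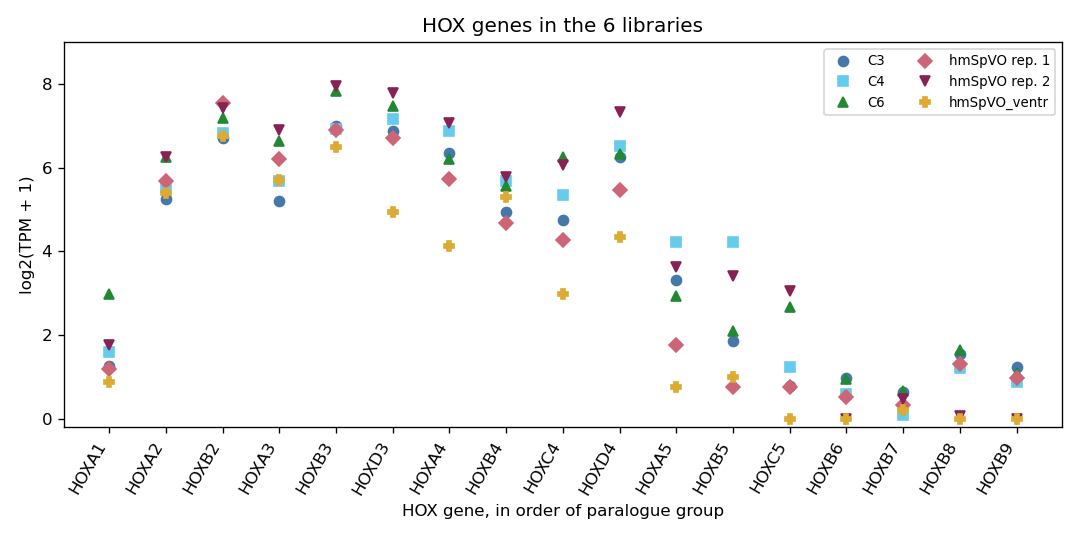
Expression of 17 HOX genes, in order of paralogue group, as log2(TPM + 1), with 1 symbol per library. Genes of groups 2 to 4 are expressed in all 6 libraries and those of groups 6 to 9 lie near 0, with HOXD4 lowest in hmSpVO_ventr at 19.3 TPM.

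The spread between the hmSpVO libraries sets the scale for all comparisons. They differed at least 4-fold at 453 of 18894 genes on the log2(TPM + 1) scale, 140 higher in replicate 1 and 313 higher in replicate 2 (183 and 254 after quantile normalization). Of the 453 genes, 144 were protein-coding. The SD of their differences was 0.77 on the log2 scale, and these libraries also differ in kit and instrument, so culture and kit cannot be told apart in them. The labels do not say whether they are separate cultures, and p-values below measure only the spread between these libraries. List percentiles below set genes against other genes of the same libraries and are not p-values for the groups. Among named genes, LBX1 was at 128 and 235 TPM and PAX3 at 144 and 92.2 TPM in replicates 1 and 2, whereas the sensory factor POU4F1 was at 1.46 and 37.0 TPM. The HOX genes of groups 4 and 5 also parted them, with HOXD4 at 43.0 and 162 TPM and HOXC5 at 0.68 and 7.31 TPM. By contrast C3 and C4, single libraries of the same kit, differed at 66 genes with an SD of 0.38.

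**Figure D2:**
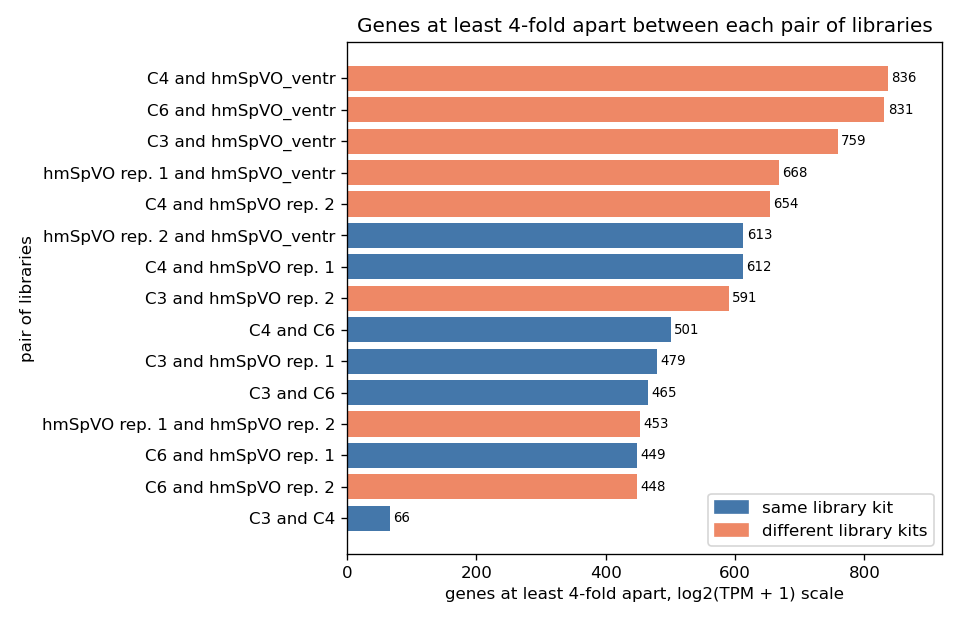
Number of genes at least 4-fold apart on the log2(TPM + 1) scale for each of the 15 pairs of libraries, with bars coloured by whether both were made with the same kit. C3 and C4 differ at 66 genes, the hmSpVO replicates at 453, and pairs with hmSpVO_ventr at 613 or more.

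The first comparisons ask how hmSpVO differs from C3 and from C4. Genes of the ventral neural tube were far lower in hmSpVO, and a set of dorsal progenitor genes was higher. The floor plate gene SPON1 was at 13.8 ± 9.86 TPM in hmSpVO against 443 TPM in C3 and 574 TPM in C4, and SHH, the ventralizing signal, at 0.945 ± 1.15 TPM against 20.6 and 27.6 TPM. The 9 tested SHH pathway targets had medians of 0.11 and -0.13 (percentiles 60.9 and 43.7), inside the random range. The sign of each median differed between the hmSpVO replicates. Members went both ways, with 4 higher and 4 lower in both hmSpVO libraries against C3, and 3 and 4 against C4. GLI1 and HHIP were lower, at 0.51 and 1.06 TPM in hmSpVO against 3.24 and 6.45 TPM in C3. BOC and GAS1 were higher, at 79.6 and 19.8 TPM against 17.9 and 8.64 TPM in C3. The medians therefore do not show whether pathway activity differed. The serotonergic neuron factor FEV was at 68.2 TPM in C3 and 78.1 TPM in C4, and at 0.8 and 0 TPM in hmSpVO replicates 1 and 2. In the other direction PAX3, a dorsal neural tube factor, was at 118 ± 36.7 TPM in hmSpVO against 10.1 TPM in C3 and 7.54 TPM in C4. GSX2, a factor of dorsal interneuron progenitors, was at 25.7 ± 8.92 TPM against 1.72 and 0.7 TPM.

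Of 16 tested genes listed for ventral progenitors and floor plate, all 16 were lower in both hmSpVO libraries than in C3, and 16 were lower than in C4, 9 and 10 of them by at least 4-fold. Their median log2 difference was -2.58 against C3 and -3.03 against C4, in each case at percentile 0 among 10000 random lists matched on expression, and 15 genes passed limma in each comparison when adjusted over the list alone. NTN1, which guides axons to the ventral midline, was at 33.9 ± 3.06 TPM against 200 TPM in C3 and 279 TPM in C4. The ventral progenitor factor NKX6-2 was at 1.84 ± 2.21 TPM against 63.8 and 65.9 TPM, while NKX6-1 remained at 60.3 ± 8.75 TPM against 94.2 and 125 TPM. Among 23 genes of ventral hindbrain and spinal neurons, 22 were lower in both hmSpVO libraries against each of C3 and C4, with medians of -2.72 and -2.79, and 16 and 17 passed when adjusted over the list alone. They included the V2 interneuron factors GATA2 (0.39 ± 0.41 TPM against 45.5 and 53.1 TPM) and GATA3 (0.7 ± 0.778 against 51.2 and 55.4 TPM). The exception in direction was PHOX2A, which serves visceral and noradrenergic neurons, at 105 ± 80.5 TPM against 42.4 and 40.8 TPM.

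Dorsal progenitor genes had medians of 0.79 against C3 and 0.87 against C4, in each case at percentile 100 among the random lists, with 10 of 17 higher in both hmSpVO libraries, and 0 and 5 passing when adjusted over the list alone. PAX7 was at 35.3 ± 4.51 TPM against 6.2 TPM in C3 and 5.91 TPM in C4, and MSX2 at 5.09 ± 0.502 TPM against 0.21 and 0.4 TPM. NEUROG1 went the other way, at 2.59 ± 1.44 TPM against 15.2 and 17.0 TPM. The 21 genes of dorsal neurons went both ways, with medians of 0.10 and 0.03. Without replicate 2 these were -0.26 and -0.24, and without replicate 1 they were 0.55 and 0. LBX1, the factor of dorsal association interneurons, was at 182 ± 75.5 TPM against 35.8 and 44.9 TPM, and TLX3, of excitatory sensory relay neurons, at 82.3 ± 43.7 TPM against 14.9 and 14.5 TPM. The catecholamine enzyme TH was at 185 ± 41 TPM against 37.2 and 40.5 TPM, although the list of monoaminergic and cholinergic genes had medians of -1.42 and -1.54.

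Genes outside the neural tube lists differed as well. CRHBP, which binds corticotropin-releasing hormone, was at 1.32 ± 0.679 TPM against 208 TPM in C3 and 198 TPM in C4. The transport protein TTR was at 64.3 TPM in C3 and 228 TPM in C4, and at 0.69 and 0 TPM in hmSpVO replicates 1 and 2. The matrix genes LUM and SULF1 were at 1.17 ± 1.03 and 3.49 ± 3.78 TPM, against 58.1 and 145 TPM in C3 and 75.5 and 212 TPM in C4. All 8 tested endoderm and epithelial genes were lower in both hmSpVO libraries, with medians of -1.22 and -1.80, among them the keratin KRT8 at 2.42 ± 1.42 TPM against 23.5 and 33.6 TPM. The filter fixed some of these directions, since APOA1 and CDH1 reached 1 TPM only in C3 and C4. SOX17, GATA4, GATA6, AFP and CDX2, of the same list, were under 1 TPM in every library and were not tested. Genes of GABA and glycine transmission had a median of -1.25 against C4, with 7 of 10 lower in both hmSpVO libraries there and against C3, and GAD1 at 25.2 ± 16.7 TPM against 70.9 and 93.6 TPM. Genes of peptides and receptors of somatosensory relay nuclei had a median of -1.28 in each case (-0.85 against C4 without replicate 1), although TAC3, a tachykinin, was at 49.0 ± 5.05 TPM against 8.35 and 5.49 TPM. Most cytosolic ribosomal protein genes were higher, with medians of 0.50 and 0.75, and RPS27 was at 10827 ± 769 TPM against 5899 and 4587 TPM. Of 22, 17 and 19 were higher in both hmSpVO libraries, 1 and 0 were lower, and 0 passed over the list alone. MIAT, a noncoding transcript kept in the nucleus, was at 122 ± 19.6 TPM in hmSpVO, 14.1 TPM in C3 and 10.3 TPM in C4.

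At least 4-fold differences against both hmSpVO libraries numbered 200 genes for C3, 52 higher and 148 lower in hmSpVO, and 244 genes for C4, 58 higher and 186 lower. With the same kit alone, hmSpVO replicate 1 differed from C3 at 479 genes, 141 higher and 338 lower, and from C4 at 612 genes, 156 higher and 456 lower. With replicate 2 alone, of the other kit, the balance turned, with 342 higher and 249 lower against C3 and 360 higher and 294 lower against C4. No gene passed limma on all genes, with lowest adjusted p of 0.778 and 0.706. At an unadjusted p under 0.05 there were 1118 and 1277 genes with the trend and 1129 and 1284 without it, which is 5.92% and 6.76% of the genes tested with the trend. Where no gene differs, a share of about 0.05 is expected at this threshold. The PAX3 difference was 3.39 ± 0.43 (SE) against C3 and 3.77 ± 0.43 against C4. This SE is moderated by limma, from 1 residual and 1.314 prior degrees of freedom. Its residual part comes from the hmSpVO pair alone, since C3 and C4 are single libraries. In simulated data for hmSpVO against C3 this test called 0 of 100 genes made 64-fold different, so a count of 0 does not bear on whether genes differed.

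**Figure D3:**
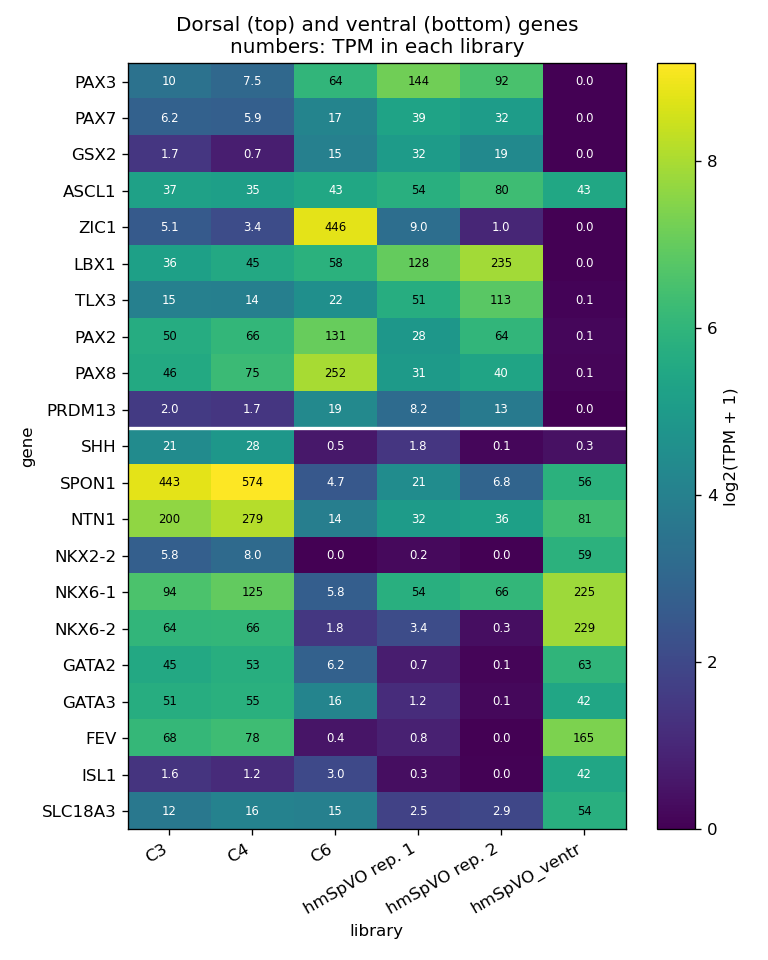
TPM of 10 dorsal genes (top) and 11 ventral genes (bottom) in each library, with colour giving log2(TPM + 1). PAX3, PAX7 and GSX2 are highest in the hmSpVO replicates and at 0 TPM in hmSpVO_ventr, SHH and SPON1 are highest in C3 and C4, and ZIC1 stands at 446 TPM in C6.

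Against C6 the median of dorsal progenitor genes turned in direction from those against C3 and C4, while ventral neuron and ribosomal protein genes kept theirs. C6 had higher levels of most, but not all, listed roof plate, midbrain and dorsal progenitor genes than hmSpVO. ZIC1, a dorsal midline factor, was at 446 TPM in C6 and at 4.98 ± 5.66 TPM in hmSpVO, and ZIC4 at 46.8 TPM against 0.205 ± 0.148 TPM. OTX2, a forebrain and midbrain factor, was at 71.4 TPM in C6 against 1.98 ± 0.566 TPM. NKX6-1 went the other way, at 5.76 TPM in C6 against 60.3 ± 8.75 TPM. FRZB, a secreted WNT antagonist, was at 14.5 TPM against 101 ± 12.9 TPM.

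Of 12 midbrain and isthmus genes, 10 were lower in both hmSpVO libraries, 5 by at least 4-fold, with a median of -1.66 and 4 passing when adjusted over the list alone. PAX8 was at 252 TPM in C6 against 35.6 ± 6.65 TPM, and DMBX1 at 26.8 TPM against 2.67 ± 2.11 TPM. Roof plate genes had a median of -1.18, with 8 of 12 lower and 4 higher in both hmSpVO libraries. The higher ones included LMX1B at 12.1 TPM in C6 against 28.0 ± 17.9 TPM, and BMP7 at 7.51 TPM against 18.9 ± 10.2 TPM. LMX1A and GDF7, of the same list, were at 0.19 and 0.93 TPM in C6 and were not tested. Dorsal progenitor genes had a median of -1.40, with 11 of 17 lower and 5 passing over the list alone, and GBX2 at 316 TPM in C6 against 39.7 ± 20.2 TPM. PAX3 and PAX7 were nevertheless higher in hmSpVO, since C6 held 64.1 and 16.7 TPM of them. Dorsal neuron genes had a median of -1.33 (-0.77 without replicate 1 and -1.83 without replicate 2), and LHX9, of the most dorsal relay neurons, was at 16.6 TPM in C6 and at 0.01 and 0 TPM in hmSpVO replicates 1 and 2. Ventral neuron genes had a median of -0.80, with 17 of 23 lower, while ventral progenitor genes had a median of 0.13, which changed sign without replicate 1. FGF pathway targets had a median of -1.51 (-0.74 without replicate 1 and -2.21 without replicate 2), with DUSP4 at 107 TPM in C6 against 31.0 ± 24.4 TPM.

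All 20 cell cycle genes were lower in both hmSpVO libraries than in C6, with a median of -1.29 and 0 passing over the list alone, and TOP2A was at 78.2 TPM in C6 against 23.7 ± 7.13 TPM. All 9 tested replication-dependent histone genes were lower, with a median of -1.87 and 4 passing over the list alone. Their level cannot be read as cell division alone, since they also served below in a test of RNA without a poly(A) tail. In hmSpVO_ventr minus hmSpVO the histone list had a median of 0.30 (percentile 89.5), although all 20 cell cycle genes were higher there. The heat shock genes HSPA6 and HSPA1A were higher in C6, with HSPA6 at 171 TPM against 1.33 ± 0.0354 TPM and HSPA1A at 489 TPM against 92.0 ± 18.4 TPM. HSPA5, of the same stress list, was at 240 TPM in C6, 253 TPM in C3 and 280 TPM in C4, against 161 ± 42.7 TPM, and the list had a median of -0.65 with 11 of 16 genes lower in both hmSpVO libraries. RN7SK, an RNA without a poly(A) tail that regulates transcription elongation, was at 5491 TPM in C6 against 90.3 ± 29 TPM. Cytosolic ribosomal protein genes had a median of 0.60, with 21 of 22 higher in both hmSpVO libraries and 0 passing over the list alone. Median-of-ratios scaling moved the differences from C6 by a median of 0.23 on the log2 scale, and those from C4 and the average by 0.10 and 0.11.

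At least 4-fold differences from C6 numbered 164, 9 higher and 155 lower in hmSpVO, of which 85 were protein-coding, 6 higher and 79 lower. Within the kit, hmSpVO replicate 1 differed from C6 at 449 genes, 82 higher and 367 lower, and replicate 2, of the other kit, at 448 genes, 193 higher and 255 lower. No gene passed limma (lowest adjusted p = 0.566), with 1003 genes at an unadjusted p under 0.05 and 987 without the trend. The 1003 are 5.31% of the genes tested, close to the share of 0.05 expected where no gene differs. The NKX6-1 difference was 3.17 ± 0.24 (SE). These single-library counts against C6 stand beside 453 genes that part the hmSpVO libraries, 144 of them protein-coding. Those against C3 and C4 were 479 and 612 with replicate 1 and 591 and 654 with replicate 2.

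Set against C3, C4 and C6 together, hmSpVO had higher levels of LBX1 and TLX3 and lower levels of ventral interneuron genes. The list of 21 dorsal neuron genes as a whole had a median of -0.48 (percentile 0.21), with 4 genes above and 4 below all of C3, C4 and C6, and its median was 0.16 without replicate 1 and -0.88 without replicate 2. CDKN1C, an inhibitor of the cell cycle, was at 285 ± 12.04 TPM in hmSpVO, and at 62.5, 74.1 and 89.3 TPM in C3, C4 and C6. LBX1 was at 182 ± 75.5 TPM against at most 57.5 TPM (C6), and TLX3 at 82.3 ± 43.7 TPM against at most 22.5 TPM (C6). P2RX3, an ATP receptor of sensory neurons, was at 61.1 ± 4.45 TPM against at most 20.2 TPM (C6). Lower in hmSpVO was SOX14, of ventral interneurons, at 0.265 ± 0.106 TPM against 15.9, 16.5 and 9.75 TPM.

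GATA3 was at 16.4 TPM or more in C3, C4 and C6, and FOXD3 at 7.38 TPM or more, against 0.7 ± 0.778 and 0.235 ± 0.233 TPM in hmSpVO. NPY, a neuropeptide, was at 6.14 TPM or more in C3, C4 and C6, and at 0 and 0.32 TPM in hmSpVO replicates 1 and 2. The Notch target HES5 and the receptor FGFR3, both of neural progenitors, were at 285 ± 159 and 295 ± 24.7 TPM, against at most 72.5 TPM (C3) and 105 TPM (C6). Ventral neuron genes had a median of -2.11, with 17 of 23 below all of C3, C4 and C6 and 19 passing limma when adjusted over the list alone. Ventral progenitor genes had a median of -1.77, with 14 passing over the list alone, but only 5 of 16 lay below all of C3, C4 and C6, and against C6 alone their median was 0.13. The pseudogene PSMC1P5 was at 104, 69.0 and 68.7 TPM in C3, C4 and C6 and listed at 0 in both hmSpVO libraries and in hmSpVO_ventr. Reads of such pseudogenes are shared with their parent genes, so that value is uncertain.

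The gap between the sets of libraries was at least 4-fold at 18 genes, 1 higher (a gene without a symbol) and 17 lower in hmSpVO, among them GATA2, NEUROD1, NXPH1 and CD9. Chance alone separates 2 libraries from 3 completely, by a gap of any size, in 20% of genes, 10% in each direction. That share bears on the counts of list genes above or below all of C3, C4 and C6, and not on the 4-fold count. No gene passed limma (lowest adjusted p = 0.539), with 1720 genes (9.10% of those tested) at an unadjusted p under 0.05 and 1565 without the trend. With replicate 1 alone, which shares the kit, 128 genes were apart, 38 higher and 90 lower, and with replicate 2 alone 217 genes, 156 higher and 61 lower, so the direction of the count turned with the library.

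The last comparison asks how hmSpVO_ventr differs from hmSpVO. Dorsal factors that lead hmSpVO were close to 0 in hmSpVO_ventr, and ventral, cholinergic and serotonergic genes were high. LBX1 and PAX3 were listed at 0 in hmSpVO_ventr against 182 ± 75.5 and 118 ± 36.7 TPM in hmSpVO, and TLX3 was at 0.06 TPM against 82.3 ± 43.7 TPM. FEV was at 165 TPM in hmSpVO_ventr, and at 0.8 and 0 TPM in hmSpVO replicates 1 and 2. The ventral progenitor factor NKX2-2 was at 58.6 TPM against 0.18 and 0 TPM. ISL1, of motor neurons, was at 41.9 TPM against 0.16 ± 0.17 TPM.

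Of 23 ventral neuron genes, 18 were higher in hmSpVO_ventr than in both hmSpVO libraries, 12 by at least 4-fold, with a median of 2.26 and 16 passing when adjusted over the list alone. Monoaminergic and cholinergic genes had a median of 2.54, with 8 of 10 higher and 9 passing over the list alone. This list shares FEV, TPH2, SLC18A3, CHAT and PHOX2A with the ventral neuron list, so the list results are not independent. The vesicular acetylcholine transporter SLC18A3 was at 53.8 TPM against 2.67 ± 0.283 TPM, the choline transporter SLC5A7 at 47.9 TPM against 0.325 ± 0.0495 TPM, and the serotonin enzyme TPH2 at 8.1 TPM against 0.13 ± 0.0707 TPM. TH went the other way, at 62.4 TPM against 185 ± 41 TPM. Ventral progenitor genes had a median of 0.67, with 9 of 16 higher, 4 lower and 1 passing over the list alone, the higher ones including NKX6-2 at 229 TPM and NKX6-1 at 225 TPM. SHH itself was at 0.34 TPM in hmSpVO_ventr, and DBX1, of more dorsal progenitors, was listed at 0 against 1.55 ± 0.509 TPM. HTR3A, a serotonin receptor subunit, was at 68.9 TPM in hmSpVO_ventr, and at 0.29 and 0 TPM in the hmSpVO replicates.

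Of 21 dorsal neuron genes, 15 were lower in hmSpVO_ventr than in both hmSpVO libraries, 8 by at least 4-fold, with a median of -1.86 (-0.91 without replicate 2) and 10 passing over the list alone. PAX2 and PAX8, of inhibitory interneurons, were at 0.13 and 0.08 TPM against 46.0 ± 25.6 and 35.6 ± 6.65 TPM. Dorsal progenitor genes had a median of -1.65, with 13 of 17 lower and 5 passing over the list alone, and NEUROG1 was higher, at 19.2 TPM against 2.59 ± 1.44 TPM. TFAP2A was at 0.06 TPM against 134 ± 54.3 TPM. Genes of GABA and glycine transmission had a median of -1.16 (-0.70 without replicate 2), with SLC32A1, the vesicular inhibitory transporter, at 2.59 TPM against 28.6 ± 7.52 TPM. Excitatory transporters differed by type, with SLC17A6 at 2.66 TPM against 55.1 ± 42.1 TPM and SLC17A8 at 45.7 TPM against 0.125 ± 0.0778 TPM. The HOX genes of groups 4 and 5 had a median of -1.93 (-2.96 without replicate 1 and -1 without replicate 2) and those of groups 1 to 3 of -0.72 (-0.88 and -0.41), with HOXA4 at 16.4 TPM against 52.5 and 134 TPM in hmSpVO replicates 1 and 2.

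All 20 cell cycle genes were higher in hmSpVO_ventr than in both hmSpVO libraries, with a median of 1.67 and 0 passing over the list alone, and MKI67 was at 11.9 TPM against 2.63 ± 0.382 TPM. The neuronal filament gene NEFL was at 1467 TPM against 262 ± 21.1 TPM and PRPH, also a neuronal filament gene, at 464 TPM against 75.3 ± 5.3 TPM. INA, another such filament gene, was at 282 TPM against 241 and 532 TPM in hmSpVO replicates 1 and 2. The list of pan-neuronal genes as a whole had a median of -0.29, which changed sign without replicate 2. Mitochondrially encoded genes had a median of -0.74, with 12 of 15 lower.

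At least 4-fold differences against both hmSpVO libraries numbered 288, 185 higher and 103 lower in hmSpVO_ventr. Within the TIANSeq kit, hmSpVO_ventr differed from hmSpVO replicate 2 at 613 genes, 274 higher and 339 lower, and across kits from replicate 1 at 668 genes, 438 higher and 230 lower. No gene passed limma (lowest adjusted p = 0.552), with 1199 genes (6.35% of those tested) at an unadjusted p under 0.05 and 1230 without the trend. When C3, C4 and C6 were fitted as one group, which the labels do not state, 33 genes passed limma, 25 higher and 8 lower, with LBX1 at an adjusted p of 0.039 and ISL1, TLX3 and HTR3A at 0.0478. With the kit as a further term 0 passed, with a lowest adjusted p of 0.0599 and 2517 genes at an unadjusted p under 0.05.

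C3 and C4 were close to each other and apart from C6. Between C3 and C4, 66 genes were at least 4-fold apart, 32 higher in C3 and 34 higher in C4, and 5 of them were protein-coding. The leading names were pseudogenes and near-identical copies, such as RPL39P3 at 0 TPM in C3 and 176 TPM in C4, and the histone copies H2AC18 (18.3 and 0 TPM) and H2AC19 (0 and 17.8 TPM). Shared reads can be split between such copies in either way, so these values are uncertain. TTR was at 64.3 TPM in C3 and 228 TPM in C4, and HOXB5 at 2.65 and 17.6 TPM. All 20 cell cycle genes were higher in C4, with a median difference of -0.33 (C3 minus C4), and all 22 ribosomal protein genes were higher in C3, with a median of 0.31.

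C6 differed from C3 at 465 genes, 150 higher in C3 and 315 higher in C6 (183 and 227 after quantile normalization), and from C4 at 501 genes, 192 higher in C4 and 309 higher in C6. SPON1 was at 4.73 TPM in C6 against 443 and 574 TPM in C3 and C4, and TFF3, a secreted trefoil peptide, at 0.43 TPM against 96.5 and 99.2 TPM. Ventral progenitor genes were higher in C3 and C4 than in C6, with medians of 2.82 and 3.37 and 15 of 16 genes in each. Dorsal progenitor genes were lower, with medians of -2.41 and -2.47 and 16 of 17 genes in each. Midbrain and isthmus genes had medians of -1.80 and -1.67, and OTX2 was at 0.39 and 0.23 TPM in C3 and C4. Hypoxia and glycolysis genes had medians of 0.78 and 0.75, with ENO1 at 1650 and 1520 TPM in C3 and C4 against 707 TPM in C6. Median-of-ratios scaling moved the differences among C3, C4 and C6 by medians of 0.12 to 0.25 on the log2 scale. These are single libraries of the same kit, with no replicate check.

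The leading genes lie at the following positions in GRCh38, from the GENCODE 29 annotation. PAX3 spans 222199888 to 222298996 on the minus strand of chromosome 2, LBX1 101226195 to 101229794 on the minus strand of chromosome 10, and TLX3 171309284 to 171312134 on the plus strand of chromosome 5. SHH spans 155799986 to 155812273 on the minus strand of chromosome 7, SPON1 13962689 to 14267884 on the plus strand of chromosome 11, and FEV 218981087 to 218985657 on the minus strand of chromosome 2. NKX6-1 spans 84491987 to 84498450 on the minus strand of chromosome 4. ZIC1 spans 147393422 to 147510293 on the plus strand of chromosome 3, and OTX2 56799905 to 56810479 on the minus strand of chromosome 14. Each of these 9 is annotated as a protein-coding gene, and TPM values cover all transcripts of a gene.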

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

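The count of protein-coding genes alone was chosen only after the data were seen. No gene passed limma in any comparison under the main settings, and 31 of 34 alternative counts of genes past the test were also 0. The exceptions were 1827 genes for hmSpVO against C6 with no filter (3 higher, 1824 lower), of which 1768 were at 0 in both hmSpVO libraries and 1616 under 1 TPM everywhere, and, with C3, C4 and C6 as one group, 1 gene against the average (PSMC1P5, adjusted p = 0.0286) and 33 for hmSpVO_ventr. The kit term added to that grouping gave 0 in both (lowest adjusted p 0.0731 and 0.0599). Among the 33 genes for hmSpVO_ventr were pseudogenes and genes without a symbol, whose values are uncertain. They included SNRPCP6 and CALCP, the latter at 29.3 TPM in hmSpVO_ventr and listed at 0 elsewhere. Without either replicate no residual degree of freedom is left, so no test was made there. No paired analysis was possible because only hmSpVO carries replicate numbers.

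Counts of genes at least 4-fold apart grew with a pseudocount of 0.1, which widens differences between low values: 743 (C3), 838 (C4), 625 (C6), 105 (average), 928 (hmSpVO_ventr), 499 (C3 against C4), 1660 (C3 against C6), 1641 (C4 against C6) and 1876 (hmSpVO pair). Among protein-coding genes alone, where fewer genes are counted, C6 had 85, C3 against C4 5, C3 against C6 296, C4 against C6 314 and the hmSpVO pair 144. Leaving out either hmSpVO replicate gave 479 to 591 (C3), 612 to 654 (C4), 448 to 449 (C6), 128 to 217 (average) and 613 to 668 (hmSpVO_ventr), since 1 library then has to meet the cutoff in place of 2. The other 40 of 64 such counts, the hmSpVO pair included, lay within 1.5 times the main ones.

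The other pseudocount and both scalings gave 3438 values of named genes, of which 916 (26.6%) moved beyond the spread of the hmSpVO pair and 26 changed sign, 0 of these among genes at least 4-fold apart. A filter leaves the value of a gene as it is, and leaving out a replicate cannot move it beyond that spread or turn a gene counted as 4-fold apart, but it turned the sign of 46 values of other genes. Of the 1250 alternative list medians 84 changed sign, 47 of them without a replicate. Only 10 of the 84 belong to medians outside the random range, and the cause was not tested. The ranges of these without either replicate were, for HOX groups 1 to 3, -0.0800 to 0.895 against C3 and -0.0275 to 0.611 against C4, with the negative values without replicate 2. Astrocyte and oligodendrocyte genes gave -0.889 to 0.171 against C4 and -0.958 to 0.0919 against the average, and dorsal neurons -0.878 to 0.161 against the average, with the positive values without replicate 1. Against C6, ventral progenitors gave -0.247 (without replicate 1) to 0.395, and hypoxia and glycolysis -0.256 (without replicate 2) to 0.553. In hmSpVO_ventr, pan-neuronal genes gave -0.369 to 0.224 (without replicate 2), and retinoic acid genes 0.0278 to 0.186, against -0.34 with both replicates. With a filter at 5 TPM the lists of HOX groups 6 to 13 and of muscle had no tested member and give no value. Depth is unknown, so its effect on low values could not be measured.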

Other observations

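The tests on MT-ND6, on the kit for the LENG8 group, on small RNAs in C6 and on dividing cells were chosen only after the result was seen, as were the genes of the next paragraph that the naming rule does not cover. Those on MT-ND6, on the kit and on dividing cells used genes picked for the same pattern. They show what the pattern itself goes against and add no separate support.

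In hmSpVO_ventr the T-box factors TBX2, TBX3 and TBX20 were at 22.0, 6.65 and 11.8 TPM, and at most 0.32, 0.11 and 0.39 TPM in the other 5 libraries. The serotonin receptor subunit HTR3B was at 7.49 TPM and the GDNF receptor RET at 28.4 TPM, against at most 0.19 and 4.52 TPM in the other 5. TTR (64.3 and 228 TPM), SERPINA1 (3.26 and 38.5 TPM) and the apolipoprotein APOA1 (1.48 and 5.02 TPM) were highest in C3 and C4, with APOA1 at most 0.26 TPM elsewhere. The choroid plexus gene FOLR1 was at 0 and 0.41 TPM in C3 and C4, and CLIC6, KCNJ13 and the liver gene AFP did not exceed 0.05 TPM there. Of the choroid plexus and ependyma list, the cilia genes FOXJ1 (21.8 and 31.2 TPM) and PIFO (8.74 and 7.06 TPM) were higher in C3 and C4 than in the other 4 libraries. Its 7 tested genes had medians of 0.62 and 0.83 for C3 and C4 minus C6 (percentiles 99.76 and 99.89), and of -1.32 and -1.53 for hmSpVO minus C3 and C4. FOS, an immediate early gene, was at 114 TPM in C6 and at most 28.7 TPM (C4) in the others. RPL39P3 was at 5225 and 3905 TPM in the TIANSeq libraries, 176 TPM in C4 and 0 in C3, C6 and hmSpVO replicate 1.

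MT-ND6, the mitochondrial gene on the strand opposite to most others, was at 2551 and 1656 TPM in the TIANSeq libraries and at most 56.1 TPM in the TruSeq ones. A difference between the hmSpVO cultures alone is argued against by hmSpVO_ventr, which lay 4.86 above the highest TruSeq library on the log2 scale. Loss of strand information in the TIANSeq values was tested on 217 genes covered by an abundant gene of the opposite strand. Their median was 0.31 higher in hmSpVO replicate 2 than in replicate 1 (percentile 99.87, 122 higher and 81 lower). Of 72 genes at least 4-fold higher in both TIANSeq libraries, 24 were such genes, against 0.827 by their share. Of 23 genes at least 4-fold lower in both, 1 was such a gene. The TIANSeq minus the TruSeq libraries gave 0.15 (percentile 97.81). hmSpVO_ventr minus the mean of C3, C4 and C6 gave -0.06 (percentile 39.3), and hmSpVO replicate 1 minus that mean -0.26 (percentile 6.54). This test was first planned with fixed bounds on the median, between which 0.31 would have left it undecided. It was changed to a percentile before the value was seen, and by that rule the prediction was met. The rule for its verdict was changed 2 times after the value was seen, each time by asking for a further kit difference. The difference for hmSpVO_ventr (percentile 39.3) did not meet the changed rule. For the 217 genes as a set, strand loss therefore cannot be told apart from other effects of kit and culture. The 24 of them among the 72, against 0.827 by their share, did part the libraries by kit. The median of the 217 does not show this. MT-ND6 has no annotated opposite-strand cover and is not among the 217. The test therefore does not bear on it or on the other 48 of the 72, and no biological explanation was tested.

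LENG8, WSB1, AHSA2P and MIAT were lower in C3 and C4 than in the other 4 libraries, with LENG8 at 14.98 and 22.3 TPM against at least 85.7 TPM. The kit is argued against, since C6 and hmSpVO replicate 1, of the same kit, lay 2.66 higher as a median of the 4 transcripts on the log2 scale. As a hypothesis, C3 and C4 may hold a lower share of RNA retained in the nucleus: 23 other such transcripts had a median of -1.24 (percentile 0), and 17 of them lay below all of C6 and the hmSpVO libraries. That list was extended by 8 genes from 16 while it was written, before any of its values were seen, and KCNQ1OT1, its remaining member, was not among the genes tested. Whether handling of the samples or the nature of C3 and C4 lies behind it remains open and untested.

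RN7SK, RMRP and RNVU1-7, RNAs without a poly(A) tail, stood at 5491, 498 and 581 TPM in C6, and RN7SK at no more than 111 TPM elsewhere. More dividing cells as the whole cause are argued against by hmSpVO_ventr, where RN7SK lay 6.06 lower on the log2 scale while the median of the cell cycle genes was 0.29 higher than in C6. As a hypothesis, more RNA without a poly(A) tail may have been carried over into the C6 library. Set against the mean of C3, C4 and hmSpVO replicate 1, 26 other small nuclear, Cajal body and nucleolar RNA genes had a median 2.21 higher in C6 (percentile 100). Of these, 19 of 26 were higher in C6 than in each of C3, C4 and hmSpVO replicate 1. Genes at 1 TPM or more in at least 1 library were used, C6 included, which favours genes high in C6 alone. This was the last of 2 versions of the test, the first having used 9 histone genes (median 1.84, percentile 100, 9 of 9), which also follow cell division, and similar small RNAs had been seen to be high in C6 before either. What sets C6 apart as a culture stays open and untested.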
